A study of Homo sapiens with 11 samples.

How the data were processed

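The measurements were Ikaros ChIP-seq peak lists from human B-ALL cell lines. The libraries were grouped by the cell line and treatment in their titles, as untreated JM1, JM1 with 20 µM CX-4945 for 1 day, untreated REH, untreated 697 and Nalm6 with CX-4945 at the same dose and time. Of the 11 libraries, the 5 inputs had no peak list analysed here. Each condition had 1 list, matched to its group by the line and treatment in the list's name. For Nalm6 there were 2 Ikaros libraries and 1 list, and whether the list came from 1 or both is not given in the sources used here. The labels name a Bethyl antibody for JM1 and REH and an affinity-purified antibody for 697 and Nalm6.

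Sequencing was paired-end, and reads were trimmed with BBDuk, per the labels' protocols. Bowtie2 2.3.4.3, MACS2 2.1.1, HOMER 4.10 and the GRCh38 build are named per the submitters' processing notes. The call settings, the control used in each call and the definition of the score are not given in the sources used here. Each peak carries a position, a whole-number score, an annotation class and a nearest transcript and gene, all made by the authors before the lists were deposited, per the file headers. The lowest score was 10 in each list and the medians were 15 in untreated JM1, 18 in treated JM1, 21 in REH, 22 in 697 and 20 in Nalm6. Scores were used to rank and describe peaks within a list, other than in the choice of 5 genes named for both JM1 lists, which set the scores of the 2 lists side by side. Read depth was not analysed here, and because deeper libraries and looser thresholds give longer lists, the number of peaks in a list cannot be read as an amount of binding. Peak numbers in the Nalm6 list ran to 73373 with 2479 numbers absent, and no Nalm6 peak was without a gene name, whereas 1043, 3103, 2917 and 511 peaks of the untreated JM1, treated JM1, REH and 697 lists were.

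Coordinates were used as deposited, with the GRCh38 sequence and the GENCODE release 44 annotation. All sequence names of the lists were found in that genome and 0 peaks ran past a sequence end. The design written beforehand assumed a column with the distance to the TSS. The files had none, so the distance was taken from the peak centre to the GENCODE TSS of the nearest transcript named in the file, which was found for 95.0 to 98.4% of peaks. A promoter peak had its centre within 1000 bp of that TSS. A second rule, added after the data had been seen, counted each gene with a TSS within 1000 bp of any part of a peak, because the first rule gives a peak to 1 gene only.

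Peaks were called shared when they overlapped by at least 1 bp. Chance overlap was estimated by 100 random placements of the peaks of 1 list within their chromosomes (20 placements for the JM1 subsets). The placements kept neither GC nor promoter content, with a median GC of 40.7% for placed treated JM1 peaks against 55.2% for the peaks themselves. An overlap above them therefore does not separate shared Ikaros sites from shared composition. Regions shared by 3 lines were merged regions with a peak of each. Shares are given with 95% exact Clopper-Pearson intervals. There was no test across samples and no p-value, since each condition had 1 list. The 23 gene lists were fixed before the data were examined, as were the comparisons, the overlap rule, the promoter window and the alternatives listed at the end, other than those said to have been added. They covered the BCL2 family, extrinsic and executioner apoptosis, CK2 subunits, the Ikaros family, B-cell transcription factors, pre-B cell receptor and B-cell surface genes, V(D)J recombination, the PI3K and inositol lipid pathway, cell cycle, genes tied to Ikaros in earlier leukemia work, glucose metabolism, adhesion and migration, chromatin regulators, drug transport with topoisomerases and nucleotide drug metabolism, the DNA damage response, the unfolded protein response and heat shock, JAK-STAT and NF-kB signalling, ribosomal proteins, and markers of T cells, myeloid cells, erythroid cells and megakaryocytes, liver, muscle and pancreas, and neurons. The number of members with a promoter peak was placed among 10000 random lists of the same size from all genes named in at least 1 peak list. After the data had been seen, random lists of protein-coding genes in 10 bins of GC content within 500 bp of the TSS were added, with the second promoter rule, since promoters with peaks were rich in GC. They were not matched on the number of TSSs per gene, and the second rule counts genes with more TSSs more readily. Percentiles in the text are from these matched lists unless stated otherwise. For JM1, the number of treated-alone members was placed among matched random draws from the genes without an untreated peak. Where a group had few such genes, as the 2 of the BCL2 family and the 2 of the B-cell transcription factors, its percentile could take few values.

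Genes were named by a rule fixed before the data were examined. It took BCL2L1, the CK2 subunits and the Ikaros family in every list, the 5 highest-scored promoter peaks per list, the 10 highest-scored promoter genes in the treated JM1 list alone, the 5 in the untreated list alone and the 5 with the highest lower score in both, up to 4 of the top-scored members per gene list and members without a peak in short lists, and the 10 genes that ranked highest in all 5 lists. Symbols starting with LOC, LINC, MIR, SNOR or RNU were left out of the ranked parts. Members named because they had a treated peak alone or no peak, and single places outside promoters, were chosen after their values had been seen.

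The hexamer TGGGAA was counted on either strand in the 200 bp at the peak centre and in windows of the same size 1000 bp to each side. Because the ratio of centre to flanks depends on base composition, its rank among 480 hexamers of the same G and C number without CpG was added after the ratios had been seen. The overlap code was tested on simulated data with a copy of the untreated JM1 list (37419 peaks) in which 60.3% of peaks were planted in a second list, and it returned 61.3%. The hexamer ratio at random places was 0.973. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all calculations and matplotlib 3.10.9 for the plots. Alternatives were a reciprocal overlap of 50%, centres within 200 bp, the top-scored 50% of each list, equal-length lists, chromosomes 1 to 22 and X only, merging of peaks closer than 1000 bp, a promoter window of 3000 bp, the promoter class of the files, a protein-coding background, a motif window of 100 bp and the shorter motif GGGAA. Results on the Y chromosome and on some single genes of these lists are not reported.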

Results

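Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with antibodies against Ikaros, a zinc finger transcription factor encoded by IKZF1, was carried out in human B-cell acute lymphoblastic leukemia (B-ALL) cell lines. JM1, REH, 697 and Nalm6 are established lines grown from leukemic B-cell precursors. The series had 11 libraries, of which 6 were Ikaros libraries and 5 were input libraries. JM1 cells were studied untreated and after 1 day with 20 µM CX-4945, an inhibitor of the protein kinase CK2. REH and 697 cells were untreated, and Nalm6 cells were treated with CX-4945 at the same dose for 1 day. Each of these conditions had 1 peak list, so every value below describes 1 list and no difference has a replicate check. JM1 and REH libraries were made with one antibody and 697 and Nalm6 libraries with another, so line and antibody cannot be separated between these pairs.

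The untreated JM1 list held 37448 peaks and the CX-4945-treated JM1 list 88692. There were 83563 peaks in the REH list, 19652 in the 697 list and 70894 in the Nalm6 list. The peaks covered 44.4 Mb in untreated JM1, 176 Mb in treated JM1, 178 Mb in REH, 16.2 Mb in 697 and 99.1 Mb in Nalm6. Median peak width was 874 bp in untreated JM1, 1185 bp in treated JM1, 1195 bp in REH, 626 bp in 697 and 862 bp in Nalm6. The widest REH peak, of 113405 bp at BAHCC1 on chromosome 17 (81371960 to 81485364), overlapped treated and untreated JM1 peaks of 72.3 and 31.6 kb at the same gene. The share of peaks in the promoter class of the authors' annotation was 26.3% in untreated JM1 (95% exact interval 25.8 to 26.7%), 16.1% in treated JM1 (15.9 to 16.3%), 16.9% in REH (16.6 to 17.1%), 40.7% in 697 (40.0 to 41.4%) and 19.2% in Nalm6 (19.0 to 19.5%). Introns held 34.7% of untreated JM1 peaks, 40.7% of treated JM1 peaks, 40.5% of REH peaks, 24.6% of 697 peaks and 38.6% of Nalm6 peaks. Exact intervals cover counting error only and say nothing about the spread between cultures. In the 19652 top-scored peaks of each list the promoter share was 34.6% in untreated JM1, 40.4% in treated JM1, 40.6% in REH and 38.2% in Nalm6, against 40.7% in the whole 697 list.

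**Figure D1:**
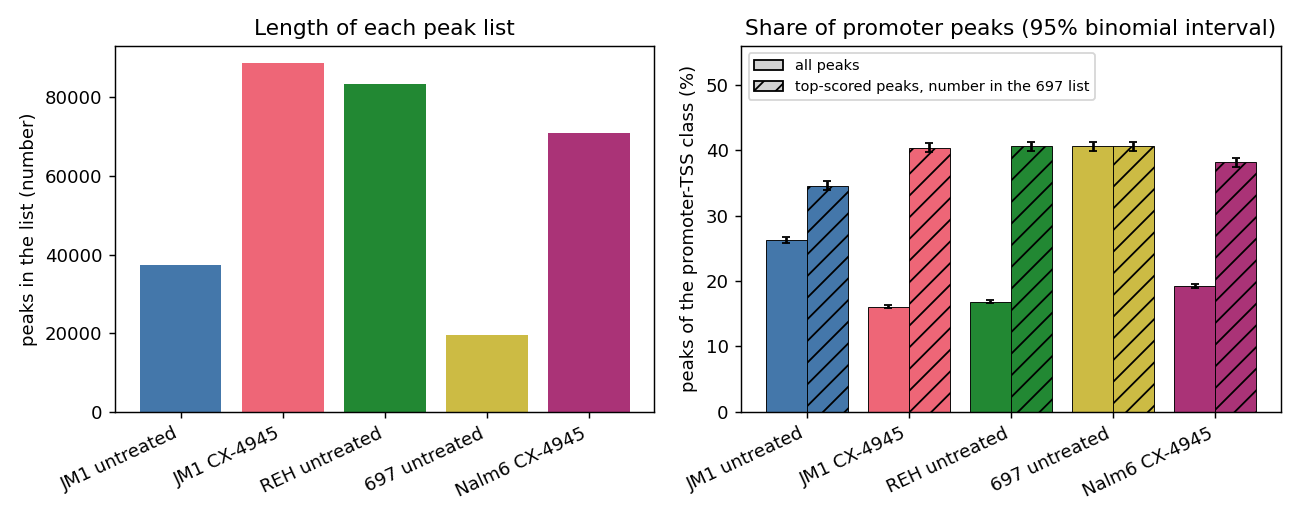
The left panel shows the number of peaks in each of the 5 lists, from 19652 in 697 to 88692 in treated JM1. The right panel shows the percentage of peaks in the promoter class with 95% exact binomial intervals, for all peaks (plain bars) and for the 19652 top-scored peaks of each list (hatched bars), where the 5 shares lie between 34.6 and 40.7%.

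The effect of CX-4945 on Ikaros binding in JM1 cells was the treatment comparison named in the series design. Of the untreated JM1 peaks, 84.1% (95% exact interval 83.7 to 84.4%) overlapped a treated peak by at least 1 bp, against 13.2% on average over 100 random placements of the peaks (12.8 to 13.6%). The placements kept neither GC nor promoter content, so the excess may reflect shared composition as well as shared sites. Of the treated peaks, 29.0% (28.7 to 29.3%) overlapped an untreated peak, against 5.15% at random. This left 62998 peaks in the treated list alone and 5968 in the untreated list alone. The treated list had 2.37 times as many peaks as the untreated list and covered 3.97 times as much sequence, and it was the longer list on every chromosome from 1 to 22 and X, with ratios from 1.65 on chromosome 19 to 3.39 on chromosome 18. Promoter peaks were shared more often than the rest, with 95.9% of untreated promoter peaks overlapped by a treated peak against 79.8% of the other untreated peaks. Treated-only peaks lay in promoters in 10.1% of cases, in introns in 43.8% and in intergenic sequence in 34.4%, whereas treated peaks that overlapped an untreated peak lay in promoters in 30.7%, in introns in 33.1% and in intergenic sequence in 18.8%. Untreated-only peaks were likewise poor in promoters, at 6.77% (6.15 to 7.44%). With a reciprocal overlap of 50% 23.4% of untreated and 9.89% of treated peaks were overlapped. With both lists limited to their 37448 top-scored peaks, 65.5% of untreated and 50.8% of treated peaks were overlapped.

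**Figure D2:**
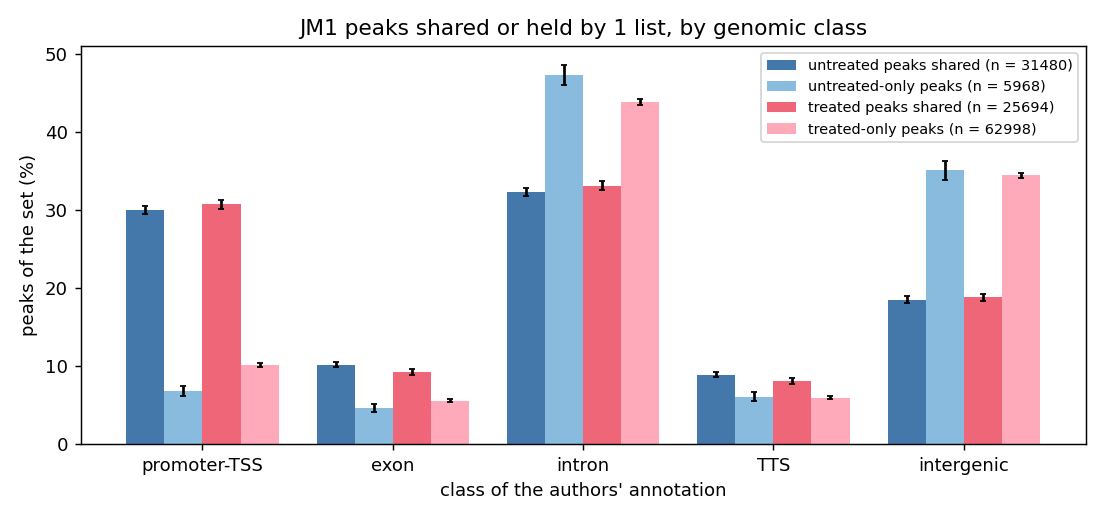
Percentage of JM1 peaks (vertical axis) in each class of the authors' annotation (horizontal axis), for untreated and treated peaks that overlapped a peak of the other JM1 list and for untreated-only and treated-only peaks; error bars are 95% exact binomial intervals. Promoters hold 30.0 and 30.7% of the shared peaks against 6.77% of the untreated-only and 10.1% of the treated-only peaks.

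The peaks found in 1 JM1 list alone were narrower and lower in score than the shared ones. Treated-only peaks had a median score of 16 and a median width of 933 bp, against 25 and 2306 bp for treated peaks shared with the untreated list. Untreated-only peaks had a median score of 13 and a median width of 467 bp, against 15 and 967 bp for the shared untreated peaks. Of the treated-only peaks, 53.9% overlapped a peak of untreated REH cells (11.8% at random) and 36.4% a peak of treated Nalm6 cells (7.83% at random). Of the shared treated peaks, 94.7% overlapped a REH peak (18.8% at random) and 85.6% a Nalm6 peak (14.0% at random).

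At the level of genes, 8818 gene names had a promoter peak (centre within 1000 bp of the transcription start site, TSS, of the nearest transcript in the file) in both JM1 lists, 7542 in the treated list alone and 2491 in the untreated list alone. That rule gives each peak to 1 gene. When any TSS within 1000 bp of any part of a peak was counted, 11662 protein-coding genes had a peak in both lists, 4599 in the treated list alone and 113 in the untreated list alone. Because this second rule counts any part of a peak, it reaches more TSSs in a list with wider peaks. Median peak width was 1185 bp in treated and 874 bp in untreated JM1. Among genes with a promoter peak in both lists, the 5 with the highest lower score of the 2 were KMT2A, which encodes a histone methyltransferase (score 379 untreated and 584 treated; chromosome 11, 118435971 to 118437493 in the untreated list), PA2G4 (214 and 211), the ribosomal protein gene RPS19 (132 and 212), SMUG1, a uracil DNA glycosylase (122 and 231), and NABP2, a single-stranded DNA binding protein (152 and 103). Scores are the authors' own and are not on a scale common to the lists, so this choice, fixed beforehand, is not an order of binding strength.

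The 10 genes with the highest-scored promoter peak in the treated JM1 list and none under their name in the untreated list were EXOC8 (score 648), EID2B (588), AC010504.1 (524), ANKRD26 (523), AC004812.2 (497), XRCC5 (477), GTF3A (472), SDHA (393), ARRDC1-AS1 (388) and DNAJA3 (331). Of these, 4 had no untreated JM1 peak near any of their TSSs. They were ANKRD26 (chromosome 10, 27100026 to 27100859), XRCC5, which encodes the Ku80 subunit of the end-joining machinery (chromosome 2, 216108946 to 216109732), SDHA, the flavoprotein subunit of succinate dehydrogenase (chromosome 5, 217823 to 219262), and DNAJA3, a mitochondrial co-chaperone (chromosome 16, 4425346 to 4426486). All 4 of these peaks were in the promoter class, and each of the 4 genes also had a peak near a TSS in untreated REH cells. EXOC8, EID2B, GTF3A and ARRDC1-AS1 had an untreated JM1 peak within 1000 bp of a TSS, for EXOC8 with a score of 17 and for EID2B with a score of 36. The names AC010504.1 and AC004812.2 had no match in the gene annotation used here.

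Among promoter peaks named in the untreated JM1 list alone, the highest scores were at ZBTB37 (72), NCKAP5L (65), SPPL2A (60), CERT1, a ceramide transfer protein (60), and BRPF1, a subunit of a histone acetyltransferase complex (59). Each of these 5 genes had a treated JM1 peak within 1000 bp of a TSS. The top promoter scores of the treated list itself were at AC231981.1 (2101), the transcription factor gene RFX2 (1520), the kinase gene STK32C (1324), the methyltransferase gene N6AMT1 (1051) and ARMC6 (696). Overlapping untreated JM1 peaks ranked 38, 27, 75, 31 and 2919 in their own list.

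Ribosomal protein genes differed most between the JM1 lists in the number of members with a peak near a TSS. Both lists covered 17 of the 34 members, and the treated list alone covered 16 more, among them RPL3, RPL5, RPS3 (score 64) and RPS23 (37). RPL4 was covered by neither. Random lists of protein-coding genes matched on GC content held 12.2 treated-alone genes on average, and 16 lay at the 98.9th percentile of those lists, which like the rule of any TSS were added after the data had been seen. With the nearest-gene rule set beforehand and random draws from all named genes, the percentile of the treated-alone count was 100, and in the next 4 paragraphs that percentile is given second, after a semicolon. RPS19 (212), RPL8 (113), RPS3 (64) and RPL15 (52) had the highest scores of the group in the treated list. All 34 members had a peak near a TSS in untreated REH cells, 11 in 697 and 25 in treated Nalm6.

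Among genes of glucose metabolism, 20 of 26 had a peak near a TSS in both JM1 lists and 6 in the treated list alone (99.5th percentile of matched lists; 99.98). The 6 were the glucose transporter gene SLC2A3, the hexokinase gene HK1 (score 48), PGK1 (24), LDHA (63), TXNIP (31) and CNR2. CNR2 encodes a cannabinoid receptor. The list fixed beforehand held such receptor genes beside genes of glucose transport and breakdown. The highest treated score of this group was at the phosphoglycerate mutase gene PGAM1 (236), followed by the insulin receptor gene INSR (75). Of 21 genes for drug transport, topoisomerases and nucleotide drug metabolism, 17 were in both lists and 4 in the treated list alone (97.5th percentile; 56.4), which were ABCB1, ABCC2, TOP2A and TPMT. ASNS (87), TOP1 (79), ABCC5 (77) and HPRT1 (67) led that group. Of 20 genes of the DNA damage response, 12 were in both lists and 8 in the treated list alone, with 5.89 in matched random lists (96.6th percentile; 99.94). The 8 included ATM (52), ATR (57) and BRCA2 (69), and the highest scores in the group were at MDM2 (136), RRM2B (108), PARP1 (80) and MDM4 (72). All 20 genes of the DNA damage response and all 26 genes of glucose metabolism also had a peak near a TSS in untreated REH cells. With 1 library per condition, percentiles describe these lists and are not tests of the treatment.

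Genes of apoptosis were largely covered in both JM1 lists. By the same rule, the untreated list covered 58.8% and the treated list 81.2% of all protein-coding genes. Coverage of the BCL2 family lay at the 93.6th percentile of matched lists in untreated and the 63.8th in treated JM1. For extrinsic and executioner apoptosis these percentiles were 88.5 and 76.7, and for the unfolded protein response and heat shock 31.7 and 86.9. In the BCL2 family, 15 of 17 members had a peak near a TSS in both, the BH3-only gene BID in the treated list alone (50.9th percentile; 68.9) and BCL2A1 in neither. PMAIP1 (31), BBC3 (26), HRK (24) and BCL2 (22) had the highest scores in the untreated list, and MCL1 (93), BBC3 (79), BCL2L1 (63) and BCL2L2 (57) in the treated list. Of 20 genes of extrinsic and executioner apoptosis, 15 were in both lists and 3 (FAS, CASP6 and BIRC3) in the treated list alone (64.2nd percentile; 96.5). BIRC2 scored 68 in the treated list. Of 20 genes of the unfolded protein response and heat shock, 14 were in both and 6 in the treated list alone (90.9th percentile; 60.1), and the chaperone gene HSP90AA1 had the highest score in each list (41 untreated, 202 treated).

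Genes of B-cell identity and signalling had peaks in most cases, where 58.8 and 81.2% of all protein-coding genes did in untreated and treated JM1. Of 30 B-cell transcription factor genes, 28 had a peak near a TSS in both JM1 lists and 2, SPI1 and FOXO1, in the treated list alone (62.9th percentile; 75.7). ETV6 (47), TCF4 (35) and ZEB2 (34) scored highest in the untreated list and POU2F2 (66), ETV6 (63) and RUNX1 (59) in the treated list. Of 27 pre-B cell receptor and B-cell surface genes, 19 were in both, CD34, CD9, MME and BLNK in the treated list alone (76.5th percentile; 92.2), and MS4A1, IL7R, CRLF2 and CD53 in neither. Of 10 genes of V(D)J recombination, 5 were in both, DCLRE1C, XRCC5 and NHEJ1 in the treated list alone (54.1st percentile; 96.4), and DNTT and XRCC4 in neither. All 22 genes of JAK-STAT and NF-kB signalling were in both. In the PI3K and inositol lipid pathway 23 of 29 were in both and 5 in the treated list alone (89.1st percentile; 99.91), with PIP4K2B (58 untreated, 155 treated) at the top in each list. Of 32 cell cycle genes 24 were in both and 6 in the treated list alone (22.2nd percentile; 99.5), and CDC7 (146) and CDK4 (124) had the highest treated scores. Of 21 genes tied to Ikaros in earlier leukemia work, 16 were in both and CTNND1 and CD34 in the treated list alone (69.6th percentile; 90.1).

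Of 30 chromatin regulator genes, 27 were in both JM1 lists and HDAC1, SUZ12 and KDM5A in the treated list alone (69.1st percentile; 95.9); KMT2A (584) and SMARCA4 (486) had the highest treated scores. Of 26 genes of adhesion and migration, 22 were in both, and CXCR5 and JAM3 in the treated list alone (64.3rd percentile; 90.1). Lists of other cell types were covered too. Of 22 T cell markers, 10 were in both, 4 in the treated list alone (35.9th percentile; 74.7) and CD5 in the untreated list alone. Of 18 myeloid markers, 9 were in both and 6 in the treated list alone (87.6th percentile; 99.8). Of 18 erythroid and megakaryocyte markers, 6 were in both, KLF1 and GP1BA in the treated list alone (0.675th percentile; 20.8) and 10 in neither. Of 22 liver, muscle and pancreas markers, 8 were in both, 3 in the treated list alone (23.9th percentile; 67.6) and 11 in neither. Of 20 neuron markers, 15 were in both and 3 in the treated list alone (43.0th percentile; 98.5). The cell cycle and neuron marker lists thus lay above the 97.5th percentile by the rule set beforehand and under the 50th against the matched lists.

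The series title names Bcl-xL, the anti-apoptotic protein encoded by BCL2L1 on chromosome 20. A promoter-class peak stood at this gene in all 5 lists. By any TSS, 8366 of the 20020 protein-coding genes had a peak in all 5 lists. The BCL2L1 promoter peak spanned 31721864 to 31723521 in untreated JM1 with a score of 17, and 31721580 to 31724127 in treated JM1 with a score of 63. In REH it spanned 31721613 to 31724125 (score 40), in 697 31722793 to 31723828 (19) and in Nalm6 31722561 to 31723998 (21). Within the scores of its own list the peak lay at the 65.0th percentile in untreated JM1, the 97.2nd in treated JM1, the 86.0th in REH, the 37.7th in 697 and the 52.0th in Nalm6. A second peak given to BCL2L1 was annotated to intron 1 of a shorter transcript, between exons 2 and 3 of the transcript drawn in the plot. It spanned 31708671 to 31709512 in untreated JM1 (score 12) and 31707931 to 31709312 in treated JM1 (20). In REH it spanned 31708427 to 31709383 (17) and in Nalm6 31708514 to 31709433 (21), and it was missing from the 697 list. Every list also had peaks overlapping the drawn transcript that were not given to BCL2L1. The highest-scored of these spanned 31684129 to 31684899 in untreated JM1 (12) and 31694012 to 31695463 in treated JM1 (31). In REH it spanned 31674926 to 31675919 (36), in 697 31664336 to 31664720 (19) and in Nalm6 31664835 to 31665222 (17). Percentiles from lists of different length do not show a change in binding, and no list was scaled to another.

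**Figure D3:**
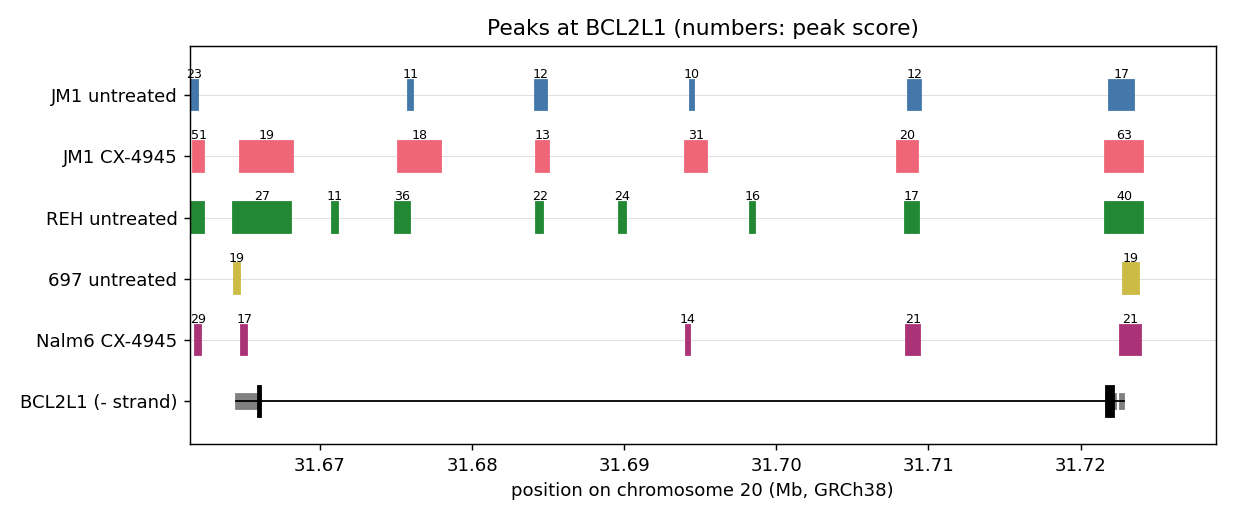
Peaks of the 5 lists (boxes, with the peak score above each) along chromosome 20 in Mb of GRCh38 around BCL2L1, whose exons are drawn in the lowest lane with coding parts in black. All 5 lists have a box at the promoter on the right, with scores of 17, 63, 40, 19 and 21 from the top lane down.

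The genes of CK2 itself carried peaks. CSNK2A2, a catalytic subunit gene, had a promoter peak on chromosome 16 in each list, with scores of 25 in untreated JM1 (58197339 to 58198294), 103 in treated JM1, 127 in REH, 62 in 697 and 73 in Nalm6. CSNK2A1, the other main catalytic subunit gene, had a peak within 1000 bp of a TSS on chromosome 20 with scores of 12, 64, 65, 17 and 28 in the same order. The regulatory subunit gene CSNK2B had a peak near a TSS in untreated JM1 (17), treated JM1 (50), REH (48) and Nalm6 (16). It had none in 697. Only the untreated JM1 list gave this peak to CSNK2B, the others giving it to a neighbouring gene. The treated JM1 peak was 9403 bp wide. CSNK2A3 had no peak near its TSS in any of the 5 lists. In the Ikaros family, IKZF1 had a promoter peak on chromosome 7 (50303480 to 50304948 in untreated JM1) with scores of 26 in untreated JM1, 46 in treated JM1, 92 in REH, 79 in 697 and 52 in Nalm6. IKZF2 scored 31, 86, 100, 17 and 23 and IKZF4 48, 81, 60, 61 and 41 in that order. Scores of different lists are not on a common scale. Within their own lists, the untreated and treated JM1 peaks of CSNK2A2 lay at the 91.7th and 99.2nd percentiles. For CSNK2A1 these percentiles were 18.15 and 97.3, for IKZF1 93.0 and 94.3, for IKZF2 96.9 and 98.7 and for IKZF4 99.6 and 98.5. Percentiles from lists of different length do not show a change in binding. The IKZF2 scores are not of 1 place. The untreated JM1 peak (chromosome 2, 213150283 to 213150597) did not overlap the peaks of treated JM1 (213151676 to 213152405), 697 or Nalm6. IKZF3, which encodes Aiolos, had a promoter peak on chromosome 17 (39864068 to 39864468) in treated JM1 (64), REH (74) and 697 (27) and none in untreated JM1 or Nalm6. IKZF5 had a peak near a TSS in the lists other than 697. Within the IKZF1 gene, Nalm6 had a peak of 249 bp over exon 4 (50376538 to 50376786) with a score of 224, where the other 4 lists had none. Nalm6 also had a peak over the coding part of exon 8 with a score of 117. The scores there were 12 in untreated JM1, 14 in treated JM1, 35 in REH and 17 in 697. In JM1 the treated-alone count of the Ikaros family lay at the 79.9th and that of the CK2 subunits at the 44.8th percentile of matched lists. Each of these groups had only 1 gene without an untreated peak near a TSS, so these percentiles say little about the group.

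**Figure D4:**
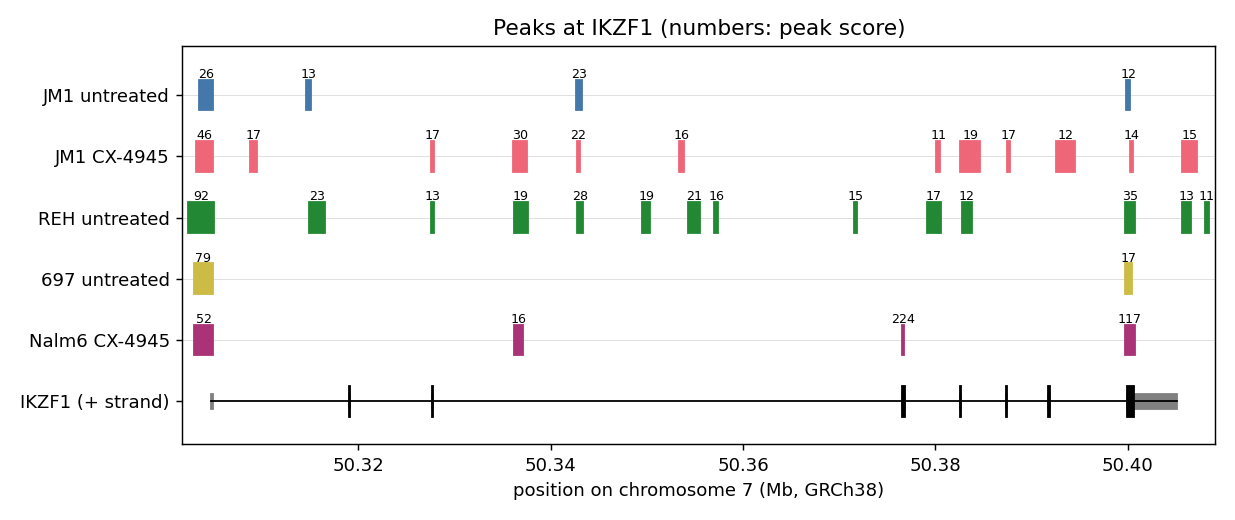
Peaks of the 5 lists (boxes, with the peak score above each) along chromosome 7 in Mb of GRCh38 around IKZF1, whose exons are drawn in the lowest lane with coding parts in black. All 5 lists have a box at the promoter on the left (scores of 26, 46, 92, 79 and 52 from the top lane down), and the Nalm6 lane alone has a narrow box over exon 4, with a score of 224.

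The design also compared Ikaros binding between JM1, REH and 697 cells. A peak of all 3 untreated lines was found in 11622 regions, against 407 on average and 465 at most over 100 random placements. Here and for the shares below, the placements kept neither GC nor promoter content. Of the 697 peaks, 92.0% (95% exact interval 91.6 to 92.4%) overlapped a REH peak, with 12.2% at random, and 67.2% (66.5 to 67.9%) overlapped an untreated JM1 peak, with 4.02% at random. Both were true of 13089 of the 697 peaks (66.6%) and neither of 1457 (7.41%). Of the untreated JM1 peaks, 85.2% (84.8 to 85.6%) overlapped a REH peak and 33.5% (33.0 to 33.9%) a 697 peak, with 13.2 and 2.07% at random. Of the REH peaks, 30.4% overlapped an untreated JM1 peak and 68.0% a treated JM1 peak, with 5.33 and 14.4% at random. Of the Nalm6 peaks, 77.3% overlapped a REH peak and 74.2% a treated JM1 peak, with 13.0% at random for each. With a reciprocal overlap of 50%, 2094 regions were shared by the 3 untreated lines and 17.6% of 697 peaks were matched in REH.

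KMT2A and RPS19 were among the 5 highest-scored promoter genes of both untreated JM1 and REH, and IER3-AS1 led both 697 and Nalm6. In REH the highest-scored promoter peaks were at AC231981.1 (517), the aspartyl-tRNA synthetase gene DARS (440), RPS19 (416) and KMT2A (341). In untreated JM1 they were at KMT2A (379), PA2G4 (214), the Polycomb gene EED (211), NABP2 (152) and RPS19 (132). In 697 they were at IER3-AS1 (331), ARHGAP45 (146), ARHGAP32 (138), STK24 (129) and HIVEP1 (129), and in Nalm6 at IER3-AS1 (257), SP1 (133), PPP2R3B (123), RAB4A (122) and NT5DC2 (120). The IER3-AS1 peak spanned chromosome 6 from 30742011 to 30744856 in 697 and from 30741915 to 30744889 in Nalm6. The overlapping peak scored 29 in untreated JM1 and 75 in REH, where it ranked 1659 and 3008.

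A promoter peak was named for 11309 genes in untreated JM1, 16360 in treated JM1, 16157 in REH, 9450 in 697 and 15725 in Nalm6, and 5103 genes had one in all 5 lists. By any TSS, the lists covered 58.8, 81.2, 81.8, 49.5 and 74.3% of the 20020 protein-coding genes in the same order. All 5 lists covered 8366 of these genes, 11108 without the 697 list, and none of the 5 covered 2945. The 10 genes that ranked highest in all 5 lists at once were RAB3IP, RBFOX2, FKBP5, RCOR1, HNRNPU, ZNF652, POGZ, TBC1D20, NEK7 and C17orf58. The RAB3IP promoter peak (chromosome 12, 69738737 to 69739691 in untreated JM1) lay at the 99.2nd percentile of scores or above in each of the 5 lists. FKBP5, a glucocorticoid-induced co-chaperone gene, had its peak at chromosome 6, 35688055 to 35688941, in untreated JM1 and at overlapping places in 697 and Nalm6, while the peaks counted in treated JM1 (35724230 to 35732710) and REH lay at another TSS of the gene.

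B-cell transcription factor genes reached the top of the GC-matched random lists, a background added after the data had been seen, in each of the 5 peak lists. A peak near a TSS was found at 28 of the 30 in untreated JM1, 27 in 697 and 30 in each of the other 3 lists, where these random lists held 17.3 in untreated JM1, 14.4 in 697, 23.8 in treated JM1, 23.8 in REH and 22 in Nalm6. This was the highest percentile of the 23 gene lists in each peak list. The random lists were not matched on the number of TSSs per gene, so genes with many TSSs may rank high for that reason. With the promoter rule and the random lists of all named genes set beforehand, the same genes lay at the 100th percentile in each peak list. With protein-coding random lists, planned as an alternative, they lay under the 97.5th percentile in treated JM1 (83.1), REH (92.55) and Nalm6 (93.88). In the same lists and order, that alternative gave 98.99, 97.22 and 99.91 for chromatin regulators. It gave 93.55, 99.98 and 99.73 for JAK-STAT and NF-kB signalling. Against the GC-matched lists, neuron markers (19 of 20) lay at the 97.85th percentile in Nalm6 and under the 97.5th in the other peak lists. SPI1, ID3 and BCL6 were the B-cell transcription factor genes without a peak in 697. The TCF3 peak led this group in 697 (score 117), FOXP1 in REH (151) and ERG in Nalm6 (72). Chromatin regulator genes (28 of 30) and the BCL2 family (16 of 17) lay at the 99.9th percentile in 697. Pre-B cell receptor and B-cell surface genes were at 19 of 27 in untreated JM1 (99.8th percentile) and at 9 of 27 in 697 (40.6th percentile). In 697, VPREB1, IGLL1, CD79A and CD79B had no peak near a TSS. The rule and the random lists of all named genes set beforehand gave percentiles of 100 and 64.6 for this group. The protein-coding alternative gave 93.9 and 3.30. Erythroid and megakaryocyte markers were at 8 of 18 in REH (0.490th percentile) and at 2 of 18 in 697 (1.65th percentile). The rule and the random lists of all named genes set beforehand gave 82.2 and 25.3 for these markers. The protein-coding alternative gave 28.2 and 2.62. Against the genes named in at least 1 of the lists, 14, 15, 14, 13 and 13 of the 23 gene lists lay at or above the 97.5th percentile in untreated JM1, treated JM1, REH, 697 and Nalm6. With GC-matched protein-coding genes these numbers were 5, 3, 4, 3 and 2.

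**Figure D5:**
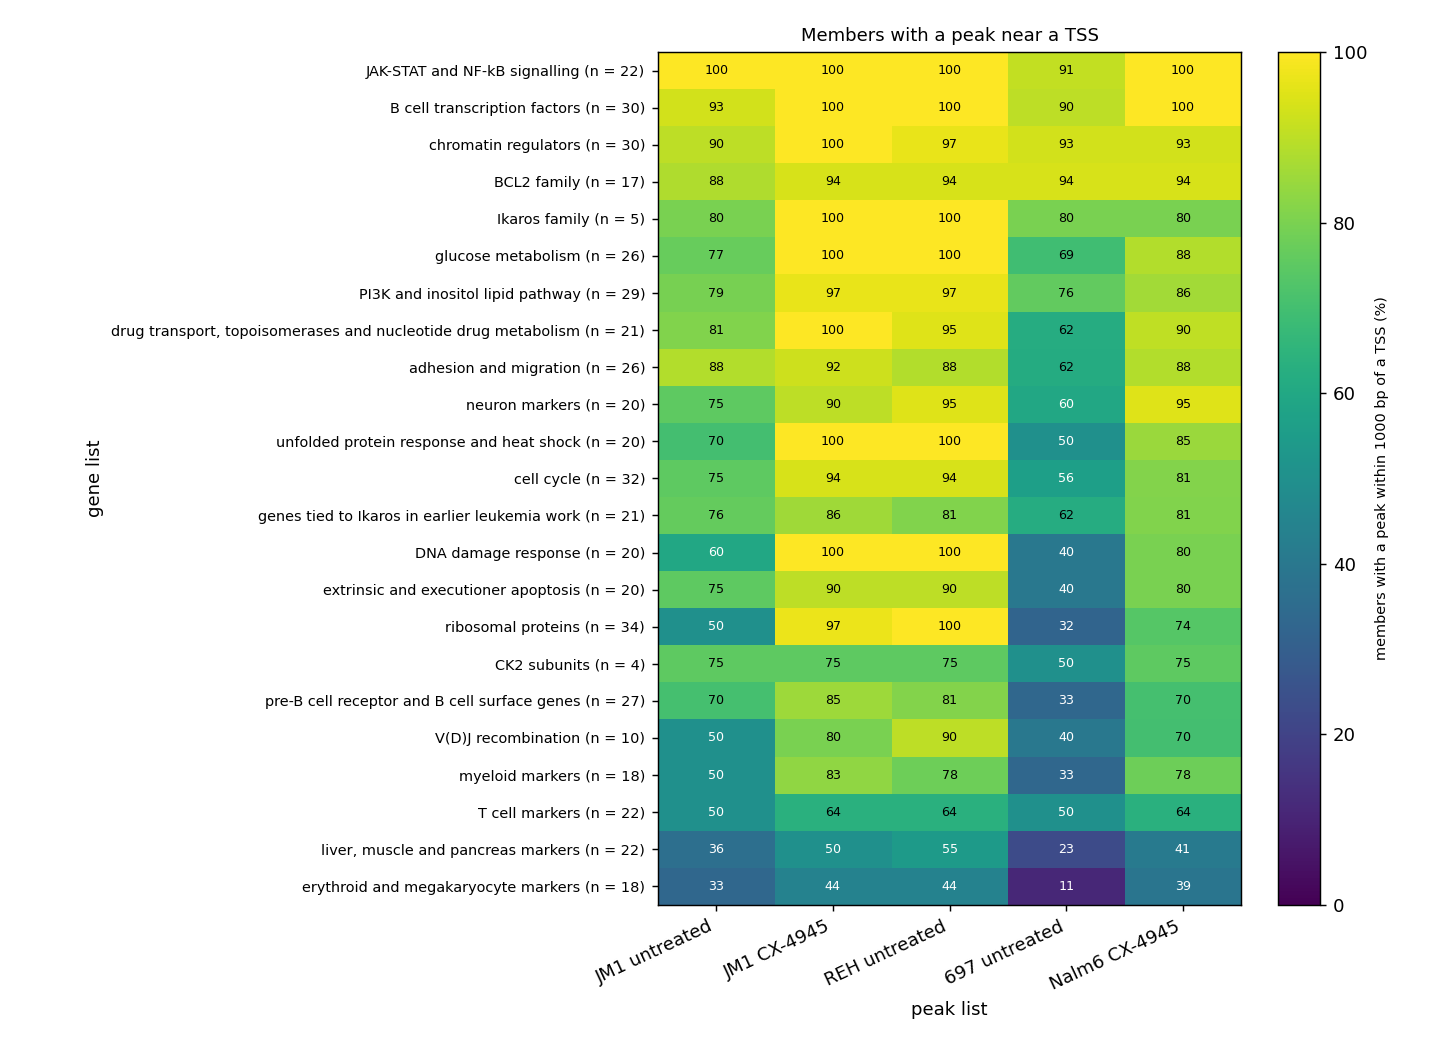
Percentage of the members of each of the 23 gene lists (rows, with the number of members) that have a peak within 1000 bp of a TSS in each of the 5 peak lists (columns); colour and printed number give the same percentage. Ribosomal proteins go from 50% in untreated JM1 to 97.1% in treated JM1, and erythroid and megakaryocyte markers stay at or under 44.4% in all 5 lists.

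The sequence TGGGAA holds the core that Ikaros zinc fingers bind. It was more frequent at peak centres than beside them in treated JM1, REH and Nalm6. Without a limit on peak width, these ratios were at most 1.08, and the sequence was less frequent in 697. In the central 200 bp it was present in 17.7% of untreated JM1 peaks, 19.3% of treated JM1 peaks, 19.3% of REH peaks, 12.4% of 697 peaks and 18.4% of Nalm6 peaks, and the ratios to the windows 1000 bp to each side were 0.988, 1.08, 1.07, 0.705 and 1.04. Peaks found in 1 JM1 list alone had the higher ratios, 1.25 in untreated-only and 1.13 in treated-only peaks, against 0.942 and 0.974 in the shared untreated and treated peaks. In wide peaks the windows to each side lay inside the peak, which may pull the ratio towards 1. Median widths were 467 bp in untreated-only and 933 bp in treated-only peaks, against 967 and 2306 bp in shared untreated and treated peaks. The sets were therefore not compared alike. The peaks were rich in GC, with a median GC content from 55.2% in treated JM1 to 69.1% in 697 and 40.7% at random places, and hexamers with CpG led each list, among them CGCGCG with a ratio of 4.82 in untreated JM1 and 8.64 in 697. Among 480 hexamers with the same number of G and C and no CpG, TGGGAA ranked 48 in untreated JM1, 23 in treated JM1, 29 in REH, 124 in 697 and 42 in Nalm6, and 7 in untreated-only, 24 in treated-only, 65 in shared untreated and 43 in shared treated peaks. The median ratio of those hexamers was likewise higher in untreated-only (1.03) and treated-only peaks (1.01) than in shared untreated (0.849) and shared treated peaks (0.882). The ratio crossed 1 in untreated JM1 (1.11) and in the shared untreated (1.09) and shared treated peaks (1.08) when GGGAA was counted.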

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

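Both tests of the IKZF1 peak in this part, and their distance limit of 25 bp, were chosen only after the result had been seen. The Nalm6 list held an IKZF1 peak outside the promoter with a score of 224, rank 3 of the list, which drew attention because the other 4 lists had no peak there. It spanned chromosome 7 from 50376538 to 50376786, and both its edges lay within 7 bp of the edges of coding exon 4 (50376533 to 50376793), a match within 25 bp that 2 of the 708 top-scored Nalm6 peaks (0.283%) had with a coding exon. DNA that carries the IKZF1 coding sequence without introns, such as an expression construct, is a candidate explanation that stays open, for the reasons that follow. The other coding stretch over 250 bp is in exon 8 (50399918 to 50400624). A high-scored Nalm6 peak lay there (score 117, rank 13). That peak began 243 bp before the exon and ended 108 bp past the coding part, inside the exon (exon end 50405101). The other 4 lists also had a peak over the coding part of exon 8 (scores of 12 to 35). The 5 shorter coding exons had no Nalm6 peak. A binding site shared with the other lines also stays open, since the 0 other lists with a peak over exon 4 are what drew attention to it, as does a site used only in Nalm6 cells or only with CX-4945, which was not tested.

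In the 697 list, 4 peaks lay on the mitochondrial sequence, on which the other 4 lists had no peak; the main comparisons of genes did not use them because the list gave them no gene, and they ranked 1, 2, 3 and 5 by score (906, 642, 583 and 357). The top-scored peak of the Nalm6 list, with a score of 4176, lay in intergenic sequence on chromosome 3 from 93470394 to 93470771 and drew attention because no comparison of genes used it; overlapping peaks ranked 1 in REH (score 1592), 5 in treated JM1 (1001) and 4 in 697 (427), and untreated JM1 had none.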

How the results depend on the processing

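The lists without peaks wider than 1000 bp, the genes by any TSS, the GC-matched random lists and the count without the 697 list were tests chosen only after the result had been seen. Of 266 values under an alternative, 133 stayed within their counting interval or within 1.5 times the count, 128 moved and 5, all of them motif ratios, turned to the other side of 1. Of those that moved, 63 were overlaps of other pairs of lists and motif ratios of single lists and are not given singly. No paired analysis was possible because each condition had 1 list, although the library titles carry replicate numbers. Leaving out a Nalm6 library was not possible with 1 list. Merging removed 0 peaks in untreated JM1, treated JM1 and REH and so tested nothing there. Where no reason is given, the cause was not tested. The unknown read depth limits every comparison of list lengths.

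A reciprocal overlap of 50% and centres within 200 bp are stricter by construction, and gave overlapped shares of 23.4 and 20.3% of untreated JM1 peaks, 9.89 and 8.56% of treated JM1 peaks, 22.2 and 20.2% of untreated JM1 peaks in REH, 30.8 and 27.2% of 697 peaks in untreated JM1, 17.6 and 25.2% of 697 peaks in REH and 30.9 and 22.4% of Nalm6 peaks in treated JM1. They left 28681 and 29858 untreated-only peaks and 2094 and 2136 regions shared by the 3 untreated lines. Equal-length lists, which hold fewer peaks, gave 65.5, 50.8, 66.8, 50.6, 65.3 and 69.0% for the same 6 overlaps, 12938 untreated-only and 18417 treated-only peaks, 6926 shared regions, 4628 genes in the treated JM1 list alone, 9851, 10011 and 9784 genes with a promoter peak in treated JM1, REH and Nalm6, and 8 gene lists at or above the 97.5th percentile in Nalm6. In these lists and in the top-scored 50% of each list BCL2L1 had a promoter peak in 4 of the 5 lists. The list without it was Nalm6 at equal length, where the peak lay at the 52.0th percentile of the full list. In the top-scored 50% it was 697, where the peak lay at the 37.7th percentile. The top-scored 50% gave 82.9, 30.1, 82.3, 61.7, 94.3 and 72.5% for the overlaps, 3194 untreated-only and 30993 treated-only peaks, 5765 shared regions, and promoter shares of 35.2% in untreated JM1, 25.1% in treated JM1, 26.4% in REH, 52.4% in 697 and 28.8% in Nalm6.

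By any TSS, 17544, 28003, 28024 and 24420 genes of all types had a peak in untreated JM1, treated JM1, REH and Nalm6, 17141 in both JM1 lists and 403 in the untreated list alone; this rule gives a peak to several genes by construction. The promoter class of the files gave 5661 genes in both JM1 lists and 8 gene lists at or above the 97.5th percentile in 697. With protein-coding genes only, 5, 1, 2, 5 and 2 gene lists reached that percentile in untreated JM1, treated JM1, REH, 697 and Nalm6, and with random lists matched on GC content 5, 3, 4, 3 and 2. Without the 697 list, 11108 protein-coding genes were in all lists. The motif ratio with GGGAA turned above 1 in untreated JM1 (1.11) and in shared untreated (1.09) and shared treated peaks (1.08), and was 1.17 in treated-only peaks. In peaks at most 1000 bp wide it turned above 1 in untreated JM1 (1.06) and shared treated peaks (1.04), and was 0.990 in shared untreated and 1.23 in treated-only peaks.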

Other observations

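The comparisons with untreated-only peaks in this part were tests chosen only after the result had been seen, and the places in the next sentences were picked after their scores had been seen. Several of the highest-scored places outside promoters in untreated JM1 also had a peak in treated JM1 and REH. The top peak of the untreated JM1 list (score 489) lay in intron 1 of LINC01056 on chromosome 20 from 63043413 to 63044744, and the overlapping REH peak (565) ranked 3 of its list, while the treated JM1 peak there (169) ranked 174, the Nalm6 peak ranked 16271 and 697 had none. An intergenic place near AC112243.1 on chromosome 4 (184965014 to 184967973) ranked 3 in untreated JM1 (score 274), 160 in treated JM1 (173) and 2 in REH (1230). Introns of AFAP1, an actin-associated adaptor gene (chromosome 4, 7863868 to 7864413; score 209), and of THBS2, a thrombospondin gene (chromosome 6, 169242434 to 169243309; 205), ranked 6 and 7 in untreated JM1, 465 and 964 in treated JM1 and 115 and 1214 in REH. In 697 an exon of CDON, a cell surface receptor gene (chromosome 11, 126062315 to 126063036), ranked 8 with a score of 144, and the Nalm6 peak there ranked 94 with a score of 94.

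The longer list of peaks in treated than in untreated JM1 cells had 3 explanations that were weighed, and all of them stay open. A deeper library or a looser threshold may account for part of the difference, with 62.6% of treated-only peaks in the lower-scored 50% of the treated list, although untreated-only peaks were also low in their own list (73.2%). A GC bias of the treated library was not decided by the median GC content of treated-only peaks (53.7%), which was under the 60.8% of all untreated peaks but above the 52.4% of untreated-only peaks, so that the test set beforehand against all untreated peaks compared unlike sets. Sites that appear only with CX-4945 were not decided either, because treated-only peaks overlapped a peak of untreated REH cells 4.56 times as often as at random, but untreated-only peaks did so 4.02 times as often and a REH peak does not show binding in untreated JM1 cells.

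The promoter-rich 697 list had 2 explanations that were weighed, and both stay open. A short list that keeps only the strongest sites was not decided, since at the length of the 697 list (40.7%) the promoter share of the other lists reached up to 40.6%, but that of untreated JM1 (34.6%) missed the limit of 5 percentage points set beforehand. The antibody of the 697 and Nalm6 libraries stays open, since at that length the share of Nalm6 (38.2%) lay between those of the 3 lists of the other antibody (34.6 to 40.6%), and the test set beforehand could not part antibody from line. A difference between the lines themselves stays open and was not tested.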
